A study of Homo sapiens with 2 samples.

How the data were processed

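Digital gene expression (DGE), a sequencing assay that counts short tags near the 3' end of polyadenylated transcripts, was carried out on H9 human embryonic stem cells and on embryoid bodies, the cell aggregates that form when embryonic stem cells are cultured in suspension. Each group had 1 library. Per the labels' protocols, H9 cells at passage 29 were moved from mouse feeder cells to Matrigel in feeder-conditioned medium with basic fibroblast growth factor. Embryoid bodies were formed from clumps of cells in low-adhesion dishes in serum-containing medium, and no time in suspension is stated in the labels. Per the labels' protocols, cDNA primed with oligo(dT) was cut with NlaIII, an adapter with an MmeI site was ligated, and the MmeI products were joined to a second adapter, amplified by 15 cycles of PCR and sequenced on an Illumina HiSeq instrument. The tags carry no molecular identifiers, so a tag is a sequenced copy and not an independent molecule.

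The deposited table has one entry per Entrez gene, 16468 in all, with symbols given by the authors. Per the file headers it holds the count of tags assigned to each gene in each library. It also holds the authors' TPM, the deposited count of the gene scaled to 1000000 tags of the library. The deposited TPM columns were tested against the counts: the same library total came out for every well-covered gene, 17728466 tags in H9 and 16260946 in the embryoid body library, so the denominator was the whole library and not the tags in the table. A count of 0 was written in the TPM columns as 0.01 by the authors and was set back to 0. Per the file headers the table also holds the authors' log2 ratio of H9 over embryoid body, a p-value and its false discovery rate (FDR). The build was hg19, per the submitters' processing notes. How tags were matched to genes, which tags were filtered out, whether strand was used and which test gave the p-values are not given in the sources used here. No gene had a count of exactly 1 in either library, while 590 genes in H9 and 592 in the embryoid body library had a count of 2. A listed 0 can therefore stand for a count below a minimum, and no upper limit was drawn from it. 2 genes with an identifier and no symbol held 0.000643% of the table's tags in H9 and 0.000592% in the embryoid body library. They were left in the table and entered no list.

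With 1 library per group no test of the conditions was possible, and no p-value was computed. The measure of each gene was log2((TPM in embryoid bodies + 1)/(TPM in H9 + 1)), a scale that understates differences of weakly expressed genes. Genes with at least 5 TPM in one or both libraries were called measured, and a gene was called higher or lower in embryoid bodies at a ratio of 2-fold or more. Each ratio of TPM, without the pseudocount, has an exact 95% interval (Clopper-Pearson, conditional on both counts), and each level an exact Poisson 95% interval. These intervals cover counting error only, not the difference between cultures or library preparations. Values of the authors' deposited table were copied and counted at an FDR of 0.001 and a 2-fold ratio, since no threshold of the authors is given in the sources used here.

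Gene lists were fixed before the data were examined, 23 in all: pluripotency, DNA methylation writers, 5-methylcytosine oxidation and removal, methyl-CpG readers, Polycomb, H3K4 methylation and H3K27 demethylation, HOX genes, developmental regulators often bivalent in embryonic stem cells, neural and ectoderm, mesoderm and heart muscle, endoderm and liver lineage, endothelial and blood, trophoblast and amnion, extracellular matrix and fibroblast, imprinted genes, germline genes silenced by DNA methylation, proliferation, cell cycle arrest and p53 targets, cytosolic ribosomal proteins, glycolysis, respiratory chain, signalling of TGF-beta, BMP and WNT, and stress response. For each list the median log2 ratio of the measured members is given with its percentile among 10000 random lists of the same size, matched on mean level in 20 bins. That percentile describes these libraries and is not a p-value. List levels are sums over every member in the table. The lists are hand-made, and none was drawn from these libraries.

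The genes named were chosen by a rule fixed at the same time. It takes the 10 highest and 10 lowest ratios among genes with at least 20 TPM in one or both libraries that carry an approved-style symbol, leaving out symbols of the LOC, FLJ, KIAA, MGC, DKFZ and open-reading-frame kinds. It adds up to 2 measured members at each end of each list, and in every case POU5F1, SOX2, NANOG, LIN28A, DNMT1, DNMT3A, DNMT3B, TET1, TET2, TET3, GAPDH and ACTB. The rule gave 103 genes, 2 of which are not reported here. Symbols are those of the table, some of them older names. Other genes named beside the rule are said to be so.

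A tag of 21 bases can occur in more than one gene. The 3'-most NlaIII tag of each gene's transcripts in GENCODE 29 was therefore searched in the transcripts of all other genes. A reference transcript was found for 15631 genes, or 94.9%. The tag was unique for 14054 genes and shared for 1556, and 21 genes had no NlaIII site. The table has no coordinates and the reference is another build than hg19, so no positions are given.

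The calculations were tested on simulated counts drawn for 10071 genes from the levels and totals of these 2 libraries. Of 50 genes each set 4-fold or 8-fold up or down, 100.0% were called, as were 0.0% of 9871 unchanged genes, and 95.0% of the intervals held the true ratio. The simulated counts held counting error alone and no change near 2-fold. They check the calculations and do not give the rate of false calls between 2 real libraries. A random list of 30 unchanged genes came out at the percentile 52.1 and, after 0.5 was added to its log2 ratios, at 100.0.

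Alternatives planned before the data were examined were pseudocounts of 0.1 and 5 TPM, no filter and a filter of 20 TPM, centring on the median of genes at 20 TPM or more in both libraries, scaling without the 100 most abundant genes, a 4-fold threshold, intervals wholly beyond 2-fold, unmatched random lists, summed list levels, and other thresholds for the authors' table. Alternatives added after the data were seen were scaling to the tags in the table, centring on the median measured gene for the gene counts alone, centring within 20 bins of mean level, and keeping only genes with a unique 3'-most tag. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.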

Results

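Transcript levels were counted by 3' tag sequencing in H9 human embryonic stem cells, an established line, and in embryoid bodies differentiated from them per the series' design text, with 1 library in each group. The stated purpose of the series was to ask how methylation and hydroxymethylation of cytosine relate to gene expression as stem cells differentiate, and the comparison here is of expression between the cells and the embryoid bodies. The TPM implied a total of 17728466 tags for the H9 library, and 10573684 (59.6% of that total) were assigned to genes in the table. For the embryoid body library the implied total was 16260946 tags, and 10468858 (64.4% of it) were assigned. Tags were listed for 15639 genes in H9 and 16098 genes in embryoid bodies. The 10 most abundant genes took 7.11% of the table's tags in H9 and 7.01% in embryoid bodies, and the 100 most abundant took 25.4% and 26.4%. No difference described here has a replicate check, and intervals cover counting error only.

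Most pluripotency transcripts were near their H9 level in embryoid bodies. Levels were higher there for many regulators of early development, neural markers, some genes of the trophoblast list and several stress genes. These groups overlap: 5 of the 8 measured trophoblast genes and 6 of the 18 measured neural genes are also among the developmental regulators. Developmental transcription factors and ligands had a median log2 ratio of 0.95, with 18 of 36 measured genes at least 2-fold higher in embryoid bodies and 0 at least 2-fold lower. Pluripotency genes had a median of 0.06, with 24 of 26 within 2-fold. The 32 proliferation genes had a median of -0.26. The immediate early genes EGR1 and FOS were 6.11-fold and 4.71-fold higher in H9, while JUN and ATF3 of the same stress list were higher in embryoid bodies.

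Of 10321 measured genes, 452 were at least 2-fold higher in embryoid bodies and 50 at least 2-fold lower, so that 90.0% of the genes past this threshold lay on the embryoid body side. For all 502 the 95% counting interval of the ratio excluded 1, which follows from the filter and the threshold at this depth. Most genes differed little, 73.3% by less than 0.5 on the log2 scale. The split depended on scaling: with tags in the table as the denominator, which shifts the log2 scale by -0.11, it was 318 higher and 89 lower, and with the median measured gene, at 0.15, set to 0 it was 272 higher and 105 lower. Weakly expressed genes lay further to the embryoid body side, with a median log2 ratio of 0.29 in the 2223 genes with a mean level under 10 TPM and 0.04 in the 2507 genes at 50 TPM or more. With ratios centred within 20 bins of mean level, the split was 214 higher and 147 lower.

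**Figure D1:**
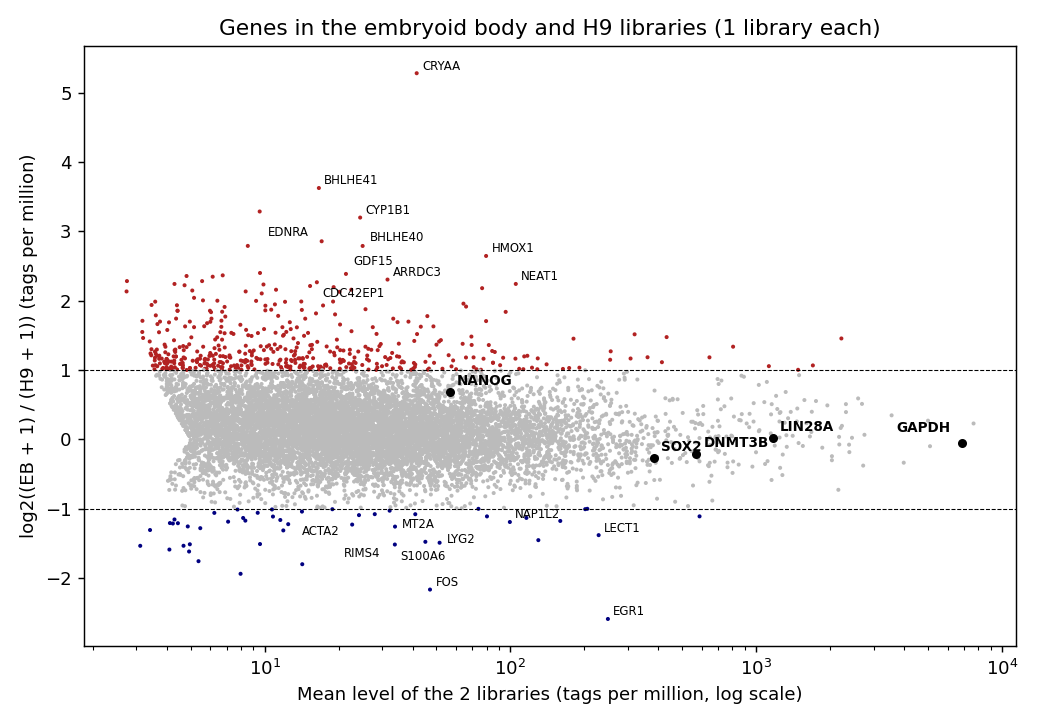
Each point is one of the 10321 measured genes, with the mean level of both libraries in TPM on a log scale (x axis) and the log2 ratio of embryoid bodies over H9 with 1 TPM added to each (y axis). Red points are the 452 genes at least 2-fold higher in embryoid bodies, blue points the 50 at least 2-fold lower, and dashed lines mark 2-fold; genes named in the text from both ends of the naming rule are labelled, with NANOG, SOX2, DNMT3B, LIN28A and GAPDH as black points, all within 2-fold.

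The highest ratio among well-expressed genes was that of CRYAA (gene 1409), which encodes a crystallin of the eye lens and small heat shock protein. It stood at 82.0 TPM in embryoid bodies and 1.13 TPM in H9, a ratio of 72.7 (95% interval 46.9 to 119), and its 3'-most tag is also found in 1 other gene. The related transcriptional repressors BHLHE41 (gene 79365) and BHLHE40 (gene 8553), which act in the circadian clock and in the response to low oxygen, were 19.3-fold (13.3 to 29.1) and 7.97-fold (6.46 to 9.94) higher. CYP1B1 (gene 1545), a cytochrome P450 of the dioxin receptor pathway, was 11.2-fold higher (8.79 to 14.5), and EDNRA (gene 1909), an endothelin receptor of neural crest derivatives, was 9.09-fold higher (6.94 to 12.1). HMOX1 (gene 3162), which breaks down heme, reached 138.0 TPM against 21.2 TPM, a ratio of 6.51 (5.83 to 7.28). The stress-induced cytokine GDF15 (gene 9518) was 5.91-fold higher (4.81 to 7.31), and the nuclear RNA NEAT1 (gene 283131), the scaffold of paraspeckles, was 4.83-fold higher (4.43 to 5.28). The arrestin-domain gene ARRDC3 (gene 57561) and the CDC42 effector CDC42EP1 (gene 11135) had log2 ratios of 2.31 and 2.27.

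At the other end stood EGR1 (gene 1958), an immediate early transcription factor, at 428 TPM in H9 and 70.05 TPM in embryoid bodies, 6.11-fold higher in H9 (95% interval 5.74 to 6.51). FOS (gene 2353), another immediate early gene, was 4.71-fold higher in H9 (4.13 to 5.39). LECT1 (gene 11061), the chondromodulin gene, was 2.62-fold higher in H9 (2.49 to 2.76). The calcium-binding protein S100A6 (gene 6277) was 2.87-fold higher in H9 (2.55 to 3.23), the metallothionein MT2A (gene 4502) 2.47-fold (2.17 to 2.82), and the smooth muscle actin ACTA2 (gene 59) 2.45-fold (2.09 to 2.88). RIMS4 (gene 140730), a synaptic protein gene, was 2.98-fold higher in H9 (2.60 to 3.42). LYG2 (gene 254773) and NAP1L2 (gene 4674) had log2 ratios of -1.49 and -1.19, but their 3'-most tags are found in 1304 and 24 other genes, so the signal cannot be assigned to them with certainty. GAPDH and ACTB, often used as reference genes, had log2 ratios of -0.06 and -0.08.

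Pluripotency transcripts were mostly within 2-fold of their H9 level. Of 32 genes, 26 were measured: 1 was higher, 1 lower and 24 neither. Their median log2 ratio of 0.06 was at the percentile 36.0 of matched random lists and moved between -0.05 and 0.09 with the scaling. Their summed level was 7376 TPM in embryoid bodies (95% interval 7334 to 7418) and 7284 TPM in H9 (7245 to 7324). LIN28A, an RNA-binding protein that blocks let-7 maturation, stood at 1175 TPM in embryoid bodies and 1158 TPM in H9, a ratio of 1.01 (0.995 to 1.03). SOX2, a core factor that neural precursors also express, was at 348 TPM against 419 TPM, a ratio of 0.830 (0.802 to 0.860). NANOG was at 69.98 TPM against 43.2 TPM, 1.62-fold higher in embryoid bodies (1.48 to 1.78). On the scale with 1 TPM added, UTF1, a chromatin-associated factor of undifferentiated cells, was the gene past 2-fold on that side. It was at 80.7 TPM against 39.5 TPM, but its log2 ratio was as low as 0.90 under the other scalings, with 0 to 2 genes of the list higher. LEFTY1, a Nodal antagonist, was past 2-fold on the H9 side, at 20.9 TPM against 43.7 TPM, and GAL, the galanin gene, had a log2 ratio of -0.41. POU5F1, which encodes OCT4, was listed at 10.6 TPM against 4.91 TPM, and its 3'-most tag is shared with 1 other gene. Its ratio was 2.17 (1.67 to 2.84) without the added 1 TPM, and its log2 ratio 0.98 with it.

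Enzymes that write and remove cytosine methylation differed little between the libraries. Of 7 genes for writing and maintenance, 6 were measured and all 6 were within 2-fold, with a median log2 ratio of -0.22 at the percentile 3.85. The de novo methyltransferase DNMT3B was the most abundant of those named, at 528 TPM in embryoid bodies and 613 TPM in H9, a ratio of 0.861 (0.837 to 0.886). The maintenance methyltransferase DNMT1 was at 53.1 TPM against 62.9 TPM, a ratio of 0.845 (0.772 to 0.924), and the chromatin remodeller HELLS had a log2 ratio of -0.23. DNMT3A had a ratio of 1.10 (1.02 to 1.18), and UHRF1, which brings DNMT1 to replicated DNA, 1.37 (1.15 to 1.65). Of 13 genes for oxidation and removal, 10 were measured, 1 of them higher and 9 neither, with a median of 0.07 at the percentile 35.6 that moved between -0.11 and 0.10 with the scaling. For the dioxygenases that make 5-hydroxymethylcytosine no difference was detectable at this depth. TET1 was at 58.7 TPM against 56.4 TPM, with a ratio of 1.04 (0.951 to 1.14). TET2 was at 9.10 TPM against 9.81 TPM, with a ratio of 0.927 (0.740 to 1.16), and TET3 was at 14.1 TPM against 12.6 TPM, with a ratio of 1.12 (0.927 to 1.35). GADD45A, a DNA damage gene also tied to demethylation, was 2.11-fold higher in embryoid bodies (1.84 to 2.42), and its log2 ratio was as low as 0.89 under the other scalings, with 0 to 1 genes of the list higher. IDH2, which makes a co-substrate of these dioxygenases, had a log2 ratio of 0.73. The glycosylases TDG and MBD4 had log2 ratios of -0.44 and -0.19, and the 3'-most tag of MBD4 is shared with 19 other genes. The 7 genes listed as methyl-CpG readers were all within 2-fold, with a median of 0.15 at the percentile 47.7. Their ends were ZBTB4 at 0.93, MBD3 at 0.63, MBD2 at -0.13 and ZBTB33 at -0.17. A place on this list does not show that a gene's protein, such as MBD3, binds methylated CpG.

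Histone-modifying complexes showed differences in single subunits. Of 29 Polycomb genes 25 were measured, 2 higher and 23 neither, with a median of 0.13 at the percentile 51.6, but 1 to 2 were higher under the other scalings. SUZ12, a core subunit of the Polycomb complex that methylates H3K27, was at 48.0 TPM in embryoid bodies and 22.9 TPM in H9, a ratio of 2.10 (1.86 to 2.37) whose log2 was as low as 0.93 under them, and PHC2, a polyhomeotic subunit, had a ratio of 2.69 (2.25 to 3.23). The methyltransferase of the same complex as SUZ12, EZH2, was at 156 TPM against 198 TPM, a ratio of 0.791 (0.752 to 0.833), and its paralog EZH1 had a ratio of 0.626 (0.547 to 0.714). Of 16 genes for H3K4 methylation and H3K27 demethylation, 2 were higher and 14 neither, with a median of 0.34 at the percentile 96.8, but 1 to 2 were higher under the other scalings. KDM5B, an H3K4 demethylase, was 2.26-fold higher in embryoid bodies (2.08 to 2.46), and the methyltransferase SETD1B 2.17-fold (1.82 to 2.60), with a log2 ratio as low as 0.87 under them. KDM5C and MLL4 had log2 ratios of -0.30 and -0.33. KDM5C, like KDM5B, removes H3K4 methylation, so the median of this list mixes genes of opposite action. HOX genes were at low levels in both libraries: 17 of 39 were in the table, none reached 5 TPM, and their levels summed to 5.95 TPM in embryoid bodies (4.84 to 7.28) and 4.46 TPM in H9 (3.53 to 5.55).

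**Figure D2:**
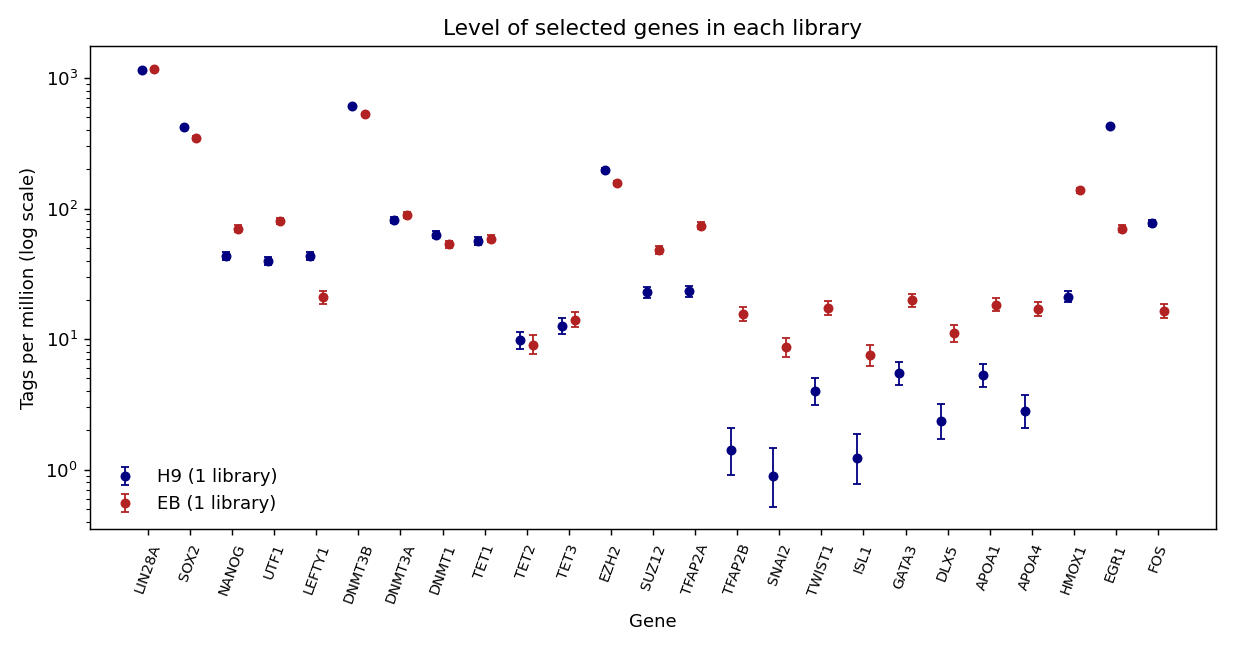
Level of 25 genes in TPM on a log scale (y axis) in the H9 library (blue) and the embryoid body library (red), with exact Poisson 95% intervals as bars, which cover counting error only. LIN28A (1158 and 1175 TPM) and the TET genes lie together in the libraries, TFAP2B (1.41 and 15.7 TPM) and SNAI2 (0.90 and 8.73 TPM) are higher in embryoid bodies, and EGR1 (428 and 70.05 TPM) is higher in H9.

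Developmental regulators that are often bivalent in embryonic stem cells, that is, marked by both H3K4 and H3K27 trimethylation, were higher in embryoid bodies as a group. Of 141 genes 36 were measured: 18 were higher, 0 lower and 18 neither, and 34 of 36 ratios were above 0. Their median of 0.95 was at the percentile 100, and under the other scalings it was between 0.59 and 0.98, with 14 to 18 genes higher. Summed levels were 881 TPM in embryoid bodies (867 to 896) and 506 TPM in H9 (495 to 516). TFAP2B, a transcription factor of neural crest and ectoderm, had 255 tags in embryoid bodies and 25 in H9, or 15.7 TPM and 1.41 TPM, a ratio of 11.1 (7.36 to 17.5). SNAI2, a regulator of cell delamination, was at 8.73 TPM against 0.90 TPM, a ratio of 9.68 (5.76 to 17.4). The lowest members were FOXF1 at -0.10 and IRX2 at -0.12. No chromatin mark was measured here, and the list is a general one.

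Lineage markers differed by lineage. Of 31 neural and ectoderm genes 18 were measured, 7 higher and 11 neither, with a median of 0.80 at the percentile 100, but 2 to 7 were higher under the other scalings. DLX5, a homeobox gene of ectoderm and neural crest, was 4.67-fold higher in embryoid bodies (3.32 to 6.70), and TFAP2A 3.18-fold (2.84 to 3.57) at 74.0 TPM. GAP43 had a ratio of 1.03 (0.872 to 1.21), and SOX3, of neural progenitors, was at 2.83 TPM against 5.36 TPM. Of 21 trophoblast and amnion genes 8 were measured, 5 higher and 3 neither, with a median of 1.13 at the percentile 100, and 4 to 5 were higher under the other scalings. GATA3, a trophoblast factor, was 3.63-fold higher (2.88 to 4.60), while TFAP2C and the keratin KRT7 had log2 ratios of 0.55 and 0.44. The other higher members were TFAP2A, ISL1, IGFBP3 and ERVWE1, the last with a log2 ratio of 1. CGA, GCM1, ELF5, PSG1 and CYP19A1 of this list were not among the measured genes. IGFBP3, ERVWE1 and these unmeasured genes are named beside the rule. Of 32 endoderm and liver-lineage genes 9 were measured, 5 higher and 4 neither, with a median of 1.44 at the percentile 100, and 4 to 5 were higher under the other scalings. The apolipoproteins APOA4 and APOA1 were 6.02-fold (4.44 to 8.31) and 3.46-fold (2.73 to 4.41) higher. APOE, which many cell types make, was at 1494 TPM against 1598 TPM, and the summed level of the endoderm list was 1711 TPM in embryoid bodies and 1742 TPM in H9, opposite in direction to the median. With a filter of 20 TPM, 4 members were left and the median was -0.022 at the percentile 22.4.

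Of 34 mesoderm and heart muscle genes 10 were measured, 2 higher and 8 neither, with a median of 0.10 at the percentile 23.3 that moved between -0.09 and 0.13 with the scaling. ISL1 and TWIST1, which are also among the developmental regulators, were 6.10-fold (3.85 to 10.1) and 4.31-fold (3.32 to 5.68) higher. The muscle genes MYL7 and TNNC1 had log2 ratios of -0.58 and -0.20. Only 2 of 25 endothelial and blood genes were measured, the vascular endothelial growth factor receptors KDR at -0.26 and FLT1 at -0.30, and FLT1 is also on the endoderm list. Their median was -0.28 at the percentile 8.21. Developmental regulators shared 6 measured genes with the neural list, 5 with the mesoderm list and 5 with the trophoblast list, so these lists are not separate evidence.

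**Figure D3:**
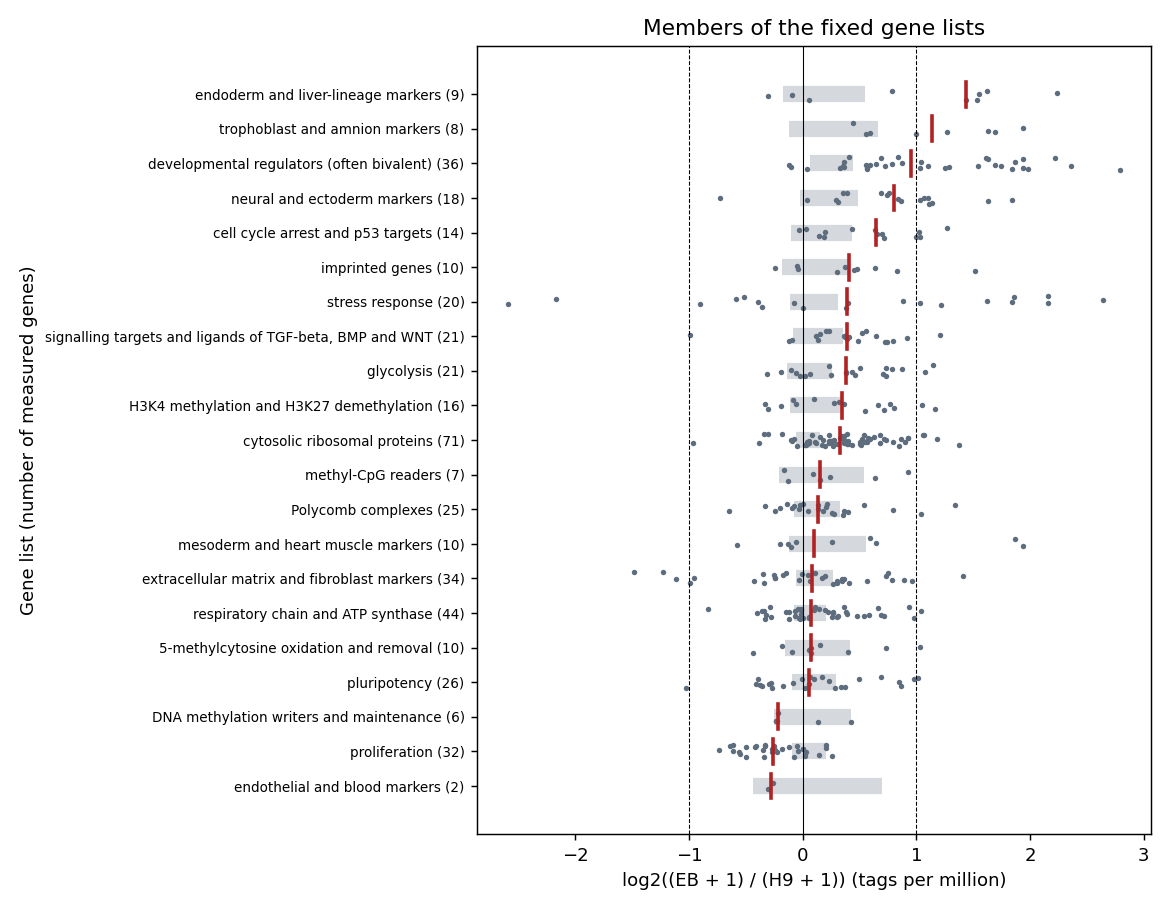
Log2 ratio of embryoid bodies over H9 (x axis, 1 TPM added to each level) of the measured members of each gene list (y axis, number of measured genes in brackets). Points are genes, red bars the list medians, and grey bars the range that holds 95% of the medians of 10000 random lists matched on level; the medians of the endoderm (1.44), trophoblast (1.13), developmental regulator (0.95), neural (0.80), arrest (0.64), imprinted (0.41), stress (0.39), signalling (0.39), glycolysis (0.38) and ribosomal protein (0.33) lists lie to the right of their grey bars and that of proliferation (-0.26) to the left.

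Matrix genes went both ways. Of 38 extracellular matrix and fibroblast genes 34 were measured, 1 higher, 3 lower and 30 neither, with a median of 0.09 at the percentile 41.9 that moved between -0.03 and 0.12 with the scaling, with 3 to 5 genes lower. The binding protein IGFBP5 was 2.72-fold higher in embryoid bodies (2.45 to 3.02) and fibronectin, FN1, 1.97-fold (1.83 to 2.11), while ACTA2, S100A6 and LOX, which encodes a collagen cross-linking enzyme, were the genes lower. LOX, with a log2 ratio of -1.12, is named beside the rule as the remaining gene of that count, after its value was seen. The summed level was 2472 TPM in embryoid bodies and 2566 TPM in H9, opposite in direction to the median. Of 24 imprinted genes 10 were measured, 1 higher and 9 neither, with a median of 0.41 at the percentile 97.8. DLK1, a paternally expressed Notch-like ligand, was at 474 TPM against 165 TPM, a ratio of 2.87 (2.75 to 2.99). PHLDA2, GRB10 and SGCE had log2 ratios of 0.83, -0.24 and -0.05. Of 20 germline genes that DNA methylation silences in somatic cells, 11 were in the table and none reached 5 TPM, with sums of 8.19 TPM in embryoid bodies (6.85 to 9.69) and 5.53 TPM in H9 (4.49 to 6.74).

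Proliferation transcripts were slightly lower in embryoid bodies and arrest transcripts higher. All 32 proliferation genes were measured and within 2-fold, and 24 had a ratio below 0. Their median of -0.26 was at the percentile 0 of matched random lists, and it was between -0.37 and -0.23 under the other scalings. The mitotic kinase PLK1 was 1.56-fold higher in H9 (1.47 to 1.67), and the spindle checkpoint kinase BUB1B 1.67-fold (1.59 to 1.76). PCNA, the replication clamp, and cyclin gene CCNE1 had log2 ratios of 0.26 and 0.21. Of 18 genes for cell cycle arrest and p53 targets 14 were measured, 3 higher and 11 neither, with a median of 0.64 at the percentile 99.96, but 1 to 4 were higher under the other scalings. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, was 2.60-fold higher in embryoid bodies (2.12 to 3.22), GADD45A is also on this list, and TP53I3 and SESN2 had log2 ratios of -0.03 and 0.03.

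Genes of translation and energy metabolism were mostly within 2-fold. Of 79 cytosolic ribosomal protein genes 71 were measured, 4 higher and 67 neither, with a median of 0.33 at the percentile 100, but 2 to 4 were higher and 0 to 1 lower under the other scalings. Of the measured members 32 have a 3'-most tag shared with another gene. Their median was 0.38, against 0.26 in the 35 with a unique tag. The ends of the list were RPLP0 at 1.37 and RPL37A at 1.18, RPL11 at -0.38 and RPL13A at -0.96, with shared tags for RPLP0 and RPL11. Of 21 glycolysis genes 2 were higher and 19 neither, with a median of 0.38 at the percentile 99.9, but 1 to 2 were higher under the other scalings. The glucose transporter SLC2A1 was 2.22-fold higher in embryoid bodies (2.12 to 2.33). PDK1, a kinase that limits the use of pyruvate in mitochondria, was 2.15-fold higher (1.92 to 2.42), with a log2 ratio as low as 0.97 under the other scalings. TPI1 and ALDOC had log2 ratios of -0.19 and -0.31. Of 49 respiratory chain genes 44 were measured, 1 higher and 43 neither, with a median of 0.08 at the percentile 64.7 that moved between -0.03 and 0.11 with the scaling, as did the number higher between 0 and 2. COX7A2, NDUFB10, ATP5G3 and ATP5L had log2 ratios of 1.04, 0.98, -0.40 and -0.83, and that of COX7A2 was as low as 0.93 under the other scalings.

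Signalling and stress genes included some of the larger differences. Of 29 targets and ligands of TGF-beta, BMP and WNT 21 were measured, 1 higher and 20 neither, with a median of 0.39 at the percentile 98.7, and 0 to 1 were lower under the other scalings. ID3, a BMP target, was 1.91-fold higher in embryoid bodies (1.74 to 2.09). CTGF was 2.00-fold higher in H9 (1.86 to 2.16), and FST had a log2 ratio of -0.12. Of 22 stress response genes 20 were measured, 8 higher, 2 lower and 10 neither, with a median of 0.39 at the percentile 99.7, and 7 to 8 were higher and 2 to 3 lower under the other scalings. The higher genes included HMOX1 and DDIT4, an inhibitor of mTOR signalling, which was 4.92-fold higher (4.08 to 5.97), and the lower genes were EGR1 and FOS. ATF3, JUN, IER3 and IER2, named beside the rule after their values were seen, had log2 ratios of 1.62, 1.03, 0.88 and -0.07. The chaperones HSPA5, HSPA1A, HSPA8, HSP90AA1 and HSPB1 and the co-chaperone DNAJB1, named beside the rule after their values were seen, had log2 ratios of -0.90, -0.59, -0.52, -0.40, -0.36 and 0.39. The tags of HSPA5, HSPA8 and HSPB1 also occur in 26, 1 and 2 other genes. With a filter of 20 TPM the median of the list was -0.035 at the percentile 18.95, while among the 16 members with a unique 3'-most tag it was 0.955 at the percentile 100. The summed level of the stress list was 3384 TPM in embryoid bodies (3355 to 3412) and 4409 TPM in H9 (4378 to 4440), opposite in direction to the median.

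The authors' deposited table listed 1003 genes higher in embryoid bodies and 105 higher in H9 at an FDR of 0.001 and a 2-fold ratio, and 423 of these were under 5 TPM in both libraries. In the authors' deposited table the p-values above 0 had different lower ends by direction. Among genes with over 1000 tags that were 2-fold apart, 104 were higher in embryoid bodies and 23 in H9. The p-value was listed as 0 for 15 of the former and 8 of the latter. Above 0, the values of the former went down to 2e-306 and those of the latter to 5.55e-15. EGR1 had a p-value of 3.22e-12 and HMOX1 one of 0 in the authors' deposited table. With such different lower ends, the p-values of genes that differ in direction are not comparable. These p-values compare the libraries and not the conditions.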

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

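The scaling to tags in the table, the centring on the median measured gene (gene counts only) and within bins of level and the restriction to unique tags were chosen after the data were seen; the other alternatives were planned. The excess of genes higher in embryoid bodies kept its direction under every alternative run, but its size did not. Genes higher and lower numbered 162 and 18 with a pseudocount of 5 TPM, 182 and 23 with a filter of 20 TPM, 34 and 2 at 4-fold, and 240 and 28 with the interval wholly beyond 2-fold. Centring on the median of genes at 20 TPM or more in both libraries gave 77 lower, and centring on the median measured gene gave 272 higher, 105 lower and 72.1% higher. Scaling to the tags in the table gave 89 lower and 78.1% higher. Centring within bins of level gave 214 higher, 147 lower and 59.3% higher. The authors' deposited table gave 1573 and 240 genes higher in embryoid bodies and in H9 at an FDR of 0.05, and 276 and 18 at 4-fold. The remaining settings gave 318 to 678 genes higher, with 381 among genes with a unique tag. Fewer genes under a stricter filter or threshold follow from its construction. For the changes with centring the cause was not tested here.

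Of 210 alternative medians of the 21 measured lists, 192 stayed within the distribution-free interval of the reported median and 14 moved beyond it. The other 4 changed the sign of a list outside the central 95% of random lists. For many lists that interval reflects the spread between genes and is wide next to the scaling shifts, as with 0.59 to 1.62 for the developmental regulators. Staying within it therefore says little about robustness. Counting lists near 0 too, 16 medians of 9 lists had the other sign. With unique tags alone the stress median rose to 0.955. The endoderm median was -0.022 with a filter of 20 TPM (percentile 22.4) and -0.026 from summed levels, and the stress median -0.035 and -0.38. The summed values follow their most abundant members. The DNA methylation writers had a median of -0.28 with median centring, -0.33 with table scaling and -0.25 with centring within bins. The developmental regulators had 0.50 with no filter and 0.59 with centring within bins. With table scaling the ribosomal proteins had 0.22 and the respiratory chain -0.034. Of 618 alternative values of the 103 named genes, 122 left the counting interval and 0 of the 2-fold calls changed sign. The latter was bound to hold, since another pseudocount cannot change a sign and the scalings moved these genes by less than 2-fold. Some calls did fall below 2-fold under the other scalings, such as those of UTF1, GADD45A, SUZ12, SETD1B, PDK1 and COX7A2. LIN28A, TET1, TET3, GAP43 and SESN2 changed sign within 2-fold under one or more scalings. No paired analysis was possible because each group has 1 library, and no library could be left out for the same reason. The most abundant transcript alone and perfect or sense tags alone were not run, since the table has one entry per gene and does not separate tags. Depth limits weakly expressed genes most, as 3 tags equal 0.169 TPM in H9 and 0.184 TPM in embryoid bodies.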

Other observations

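The 6 groups in the next paragraphs were drawn up after the highest and lowest genes had been seen, and each was tested on its members not seen before. The tests of scaling, low counts, level-dependent shift, background, swapped labels and a split library were also chosen after results had been seen.

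Genes drawn up as responding to low oxygen were higher in embryoid bodies as a group. Of 42 measured genes 19 were higher and 1 lower, a count that includes genes seen before the list was drawn up. Among the 27 not seen before, 5 were higher and 0 lower, 5 had a ratio below 0, and their median log2 ratio of 0.58 was at the percentile 100 of matched random lists. NDRG1 was at 15.4 TPM in embryoid bodies and 3.10 TPM in H9, AK4 at 116 TPM and 53.5 TPM, and the mitophagy receptor BNIP3 at 89.8 TPM and 46.5 TPM. The glycolysis genes with the highest ratios, SLC2A1 at 1.15 and PDK1 at 1.08, are on this list and had been seen before. Other glycolysis genes were not put on it and went both ways. Their log2 ratios ran from -0.31 for ALDOC, -0.19 for TPI1 and -0.02 for LDHA to 0.78 for PGAM1 and 0.87 for HK1. The choice of members therefore bears on the count over all 42 genes. Genes of the ATF4 response to amino acid shortage had a median of 0.61 in 21 genes not seen before, 4 of them higher, at the percentile 100, with CHAC1 at 6.15 TPM against 1.07 TPM and PSAT1, of serine synthesis, at 289 TPM against 172 TPM. Targets of the oxidative stress factor NRF2 had a median of 0.33 in 19 genes not seen before, at the percentile 98.2. Of these 1 was higher, SRXN1 at 42.5 TPM against 16.1 TPM with a tag that occurs in 1 other gene, and 3 had a ratio below 0, among them PGD at 136 TPM against 166 TPM. What sets these levels was not tested. The hypoxia list shares DDIT4, STC2 and VEGFA with the ATF4 list.

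Cholesterol and lipid synthesis genes were slightly lower in embryoid bodies as a group. Among 29 genes not seen before 0 were higher, 1 was lower and 18 had a ratio below 0, and their median of -0.20 was at the percentile 0.03, with SQLE at 99.01 TPM in embryoid bodies and 172 TPM in H9 and MVD at 27.9 TPM and 53.9 TPM. Others went the other way, such as SC5DL at 52.2 TPM and 26.6 TPM and FADS1 at 39.05 TPM and 25.2 TPM. Neural crest genes not seen before had a median of 0.42 in 11 genes, at the percentile 97.3 and within the central 95% of random lists. Of these 1 was higher, NR2F2 at 18.1 TPM against 4.57 TPM, and 2 had a ratio below 0, RET at 16.1 TPM against 23.7 TPM and KIT at 16.9 TPM against 19.2 TPM. One hypothesis was not borne out: growth factor and ERK response genes were predicted to be lower in embryoid bodies after EGR1 and FOS, yet the 19 not seen before had a median of 0.47 at the percentile 98.9. Of these 2 were higher, DUSP1 and DUSP5, 1 was lower, the immediate early gene ARC at 1.54 TPM against 5.30 TPM, and 4 had a ratio below 0. Over all 27 measured members 3 were higher and 3 lower.

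The first pattern weighed is the excess of genes higher in embryoid bodies, 452 against 50. Scaling alone reduced it but did not remove it, since the share of genes past 2-fold on that side was 82.4% with the median of genes at 20 TPM or more in both libraries set to 0, 78.1% with table scaling and 72.1% with the median measured gene set to 0, nor did low counts, with 88.8% at 20 TPM or more, nor shared tags, with 89.9% among genes with unique tags. An even background of tags in the embryoid body library is also argued against, because the 829 genes listed at 0 in H9 had a median of 0.18 TPM there, against a median difference of 10.3 TPM in the higher genes. A shift between libraries that varies with level stays open: with centring within bins of level the share was 59.3%, near an even split, so most of the excess may be a property of the libraries, although a wide rise of weakly expressed genes in differentiating cells would give the same value. List percentiles are matched on level and are less exposed to such a shift.

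The second pattern is the similar level of pluripotency transcripts in both libraries. Swapped labels are argued against by the developmental regulators, with a median log2 ratio of 0.95 towards embryoid bodies and 18 genes higher against 0 lower. One library split into both columns is excluded, since the chi-square of the counts was 31.9 per degree of freedom over 14723 genes, where a split would give values near 1. An early stage of differentiation and a mixture of differentiated and undifferentiated cells were not tested and stay open, as the labels give no time in suspension.

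The third pattern is the low listed level of POU5F1, 10.6 TPM in embryoid bodies and 4.91 TPM in H9, where measured pluripotency genes had medians of 64.6 TPM and 43.4 TPM. The 3'-most tag of POU5F1 occurs in 1 other gene, as needed for a 3'-most tag shared with pseudogenes or paralogs, so tags matching both may have been left out by the authors' assignment, of which no description was at hand. Across the table, genes with a shared tag had medians of 6.64 TPM in embryoid bodies and 5.28 TPM in H9, against 11.1 TPM and 9.48 TPM with a unique tag. A shared tag did not always go with a low level. RPL11, whose tag also occurs in 1 other gene, was at 2364 TPM in embryoid bodies and 3078 TPM in H9. The shared tag therefore does not settle why POU5F1 was listed so low. No biological explanation was tested, and the ratio of POU5F1 is best not read as a change of OCT4.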
